A study of Escherichia coli with 12 samples.

How the data were processed

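RNA was sequenced from Escherichia coli K-12 strains that overexpressed the cyclic AMP receptor protein (CRP), a transcription factor that activates genes for the use of carbon sources other than glucose. Per the labels, the strains carried wild-type CRP (WT), a variant with glutamine (K100Q) or arginine (K100R) in place of the lysine K100, or the AR1-/AR2- variant. AR1 and AR2 are the activating regions through which CRP contacts RNA polymerase, and the labels name this strain as the negative control. The medium was tryptone broth at pH 7 with 22 mM glucose, cells were taken at an optical density of about 1.8, and each of the 4 strains gave 3 libraries. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with the ScriptSeq v2 Complete kit. The labels do not say whether replicates were separate cultures, so p-values measure the spread between libraries, which may be technical.

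The deposited count files hold 1 column of read counts per library for 4451 genes, followed by 5 summary lines. Per the submitters' processing notes, the tools were cutadapt, TopHat2, HTSeq 0.6.1 and DESeq2 1.14.1, without versions for cutadapt and TopHat2. The genome build is not given in the sources used here, and neither is the strand setting of the counting, so reads from a gene and an antisense or overlapping partner cannot be separated. The authors also deposited a table for each of 6 comparisons with mean normalized counts, log2 fold changes and their standard errors, and adjusted p-values, per the file headers. The largest adjusted p-value kept in those deposited tables was 0.1. They were used only to set the authors' calls beside the calls made here. No column of the count files was left unused.

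Symbols were matched to a reference gene table that was used only for names, biotype and coding length; 4237 genes matched directly, 200 by a synonym, and 14 did not match. The ribosomal RNA genes and insL1 have near-identical copies, so their reads could be divided between copies or left uncounted, and their values are uncertain.

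The summary lines stayed out of library sizes and tests. Reads in no annotated gene made up between 4.1% and 4.93% of a library's reads in AR1-/AR2-, and between 5.6% and 12.1% in the other strains. Ambiguous reads averaged 9.31% in AR1-/AR2-, 7.01% in WT, 6.64% in K100Q and 5.2% in K100R. Total gene counts were between 1643373 and 2523208 in 11 libraries and 3416 in the second K100Q library. Levels are given as CPM, scaled by the trimmed mean of M values (TMM). A floor of 3 counts corresponds, after this scaling, to between 1.1 and 2.34 CPM in the 11 deeper libraries and to 371 CPM in the second K100Q library. Floors and intervals cover counting error only. Group levels are mean ± SD over 3 libraries, except in K100Q, where they are taken over replicates 1 and 3 (n = 2).

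Differences between strains were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion and 1 coefficient per strain fitted to all 12 libraries. edgeR's filter by group left 3391 genes. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Every adjusted p of a gene below comes from this test unless another tool is named. Median standard errors of the log2 fold changes were between 0.311 and 0.359. The tests, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined.

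Gene lists were written from textbook knowledge of CRP and E. coli physiology. The 21 lists cover class I and class II CRP promoters, lactose and maltose, galactose, pentoses and methylpentoses, sugar alcohols and amino sugars, and glycerol. They also cover sugar uptake by the phosphotransferase system (PTS), the tricarboxylic acid (TCA) cycle with the glyoxylate shunt and gluconeogenesis, acetate metabolism and protein acetylation, amino acid catabolism, nucleosides, and flagella and chemotaxis. The others are curli, acid resistance, general stress (RpoS), heat shock, ribosomal proteins, anaerobic respiration and fermentation, iron uptake, and ribosomal RNA. No list of transfer RNA genes was tested. Some genes belong to more than 1 list. A list was tested with limma's camera (limma 3.58.1) if it had at least 5 tested members, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. The 7 curli genes had too few counts, and 0 of them were tested. Other lists were tested in part, among them 27 of 52 flagella and chemotaxis genes, 19 of 30 iron uptake genes, 7 of 22 ribosomal RNA genes and 5 of 9 class I genes. Camera with an estimated correlation, which allows for genes of an operon moving together, and limma's fry were run as alternatives. Member counts are given over all genes tested and adjusted over the list alone. With members that had no read in a strain set to their bound, the list medians did not move.

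Named genes are crp and cyaA. For WT with AR1-/AR2- and the 3 comparisons among WT, K100Q and K100R they are also the 10 highest and 10 lowest log2 fold changes. These were taken among called genes with a mean of at least 10 CPM over the 12 libraries and with the 3 libraries of a strain all above or all below the 3 of the other. For K100Q and K100R with AR1-/AR2- the rule takes 5 and 5. Up to 4 members of each list, those with the smallest p, are added. The rule can hardly name genes higher in K100Q, because most genes are near 0 in the second K100Q library. For genes without a read in a strain, the fold is a lower bound against a floor of 3 counts over that strain. For genes with 1 to 3 counts in a strain, an exact binomial interval at 95% confidence is given.

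The steps were tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each fold size. Of genes changed 2-fold, 40% were recovered in WT with AR1-/AR2-, 42% in K100Q with AR1-/AR2- and 34% in K100R with AR1-/AR2-. The shares were 20% in K100Q with WT, 38% in K100R with WT and 48% in K100Q with K100R. At 4-fold, in that order, they were 98%, 88%, 92%, 88%, 92% and 94%. At 1.5-fold they were 4%, 6%, 6%, 0%, 8% and 10%, and at 8-fold 100%, 94%, 100%, 98%, 100% and 100%. Of the 3122, 3118, 3107, 3122, 3111 and 3118 genes left unchanged, 1, 5, 7, 11, 9 and 8 were called. The 11 in K100Q with WT and the 9 in K100R with WT were called beside many changed genes. The adjusted p allows more false calls where more genes are called. These numbers therefore cannot be set against the 7 genes called in the data of each. How many of those 7 are false calls was not tested, and some may be.

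The alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of 10 CPM in 3 libraries, a fit of only the 6 libraries compared, limma's voom with quality weights, and thinning to the shallowest library. Further ones left out crp with the ribosomal and transfer RNA genes, added the replicate number as a block, or left out each library in turn. After the data were seen, fits of 11 libraries (without the second K100Q library) and 10 libraries (also without the second K100R library), DESeq2 on the 11 libraries, the 11 libraries thinned to the shallowest of them, and a fit with a smooth trend on coding length removed (span 0.3) were added. The length trend was fitted to log2 CPM with a prior count of 2. Genes without a read in any library of a fit were left out.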

Results

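Transcript counts were collected from 12 libraries, 3 from each of 4 E. coli strains that overexpressed WT, K100Q, K100R or AR1-/AR2- CRP. In 11 libraries, between 1643373 and 2523208 reads were assigned to genes. The second K100Q library had 3416 such reads over 835 genes.

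The overexpressed gene, crp, had 16740 ± 619 CPM in AR1-/AR2- and 20840 ± 2073 CPM in WT (SD, n = 3 each). It had 20620 ± 2674 CPM in K100Q (n = 2) and 18580 ± 1383 CPM in K100R (n = 3). Its log2 fold change against AR1-/AR2- was 0.32 in WT (adjusted p = 0.444), 0.06 in K100Q (adjusted p = 0.896; −0.09 with DESeq2 size factors) and 0.15 in K100R (adjusted p = 0.726; −0.03 with the length trend removed), so crp was not called in any of them. With all libraries thinned to the shallowest, crp was called as higher in WT (1.02, adjusted p = 7.41e-04; up to 0.716 over the alternatives), K100Q (1.01, 8.23e-04; up to 0.991) and K100R (0.78, 0.00665; up to 0.915), and in no other alternative. The gene for adenylate cyclase, cyaA, which makes the cyclic AMP that CRP binds, had 242 ± 9.7 CPM in AR1-/AR2- and 392 ± 39.5 CPM in WT. It was higher in WT with a log2 fold change of 0.70 (SE 0.28; adjusted p = 0.0379; 2.38e-04 to 0.208 over the alternatives) and in all 3 WT libraries. The call of cyaA ended without AR1-/AR2- replicate 1 (log2 fold change of cyaA, WT vs AR1-/AR2-, adjusted p = 0.0762), AR1-/AR2- replicate 2 (0.115), WT replicate 1 (0.127), WT replicate 2 (0.0679) or WT replicate 3 (0.0743), and also with DESeq2 size factors (0.099) and with DESeq2 (0.208). In K100Q and K100R, cyaA was not called (0.66, adjusted p = 0.0687, and 0.64, adjusted p = 0.0564), but it was in 7 (4.67e-04 to 0.372 over the alternatives) and 8 alternatives (4.67e-04 to 0.182).

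**Figure D1:**
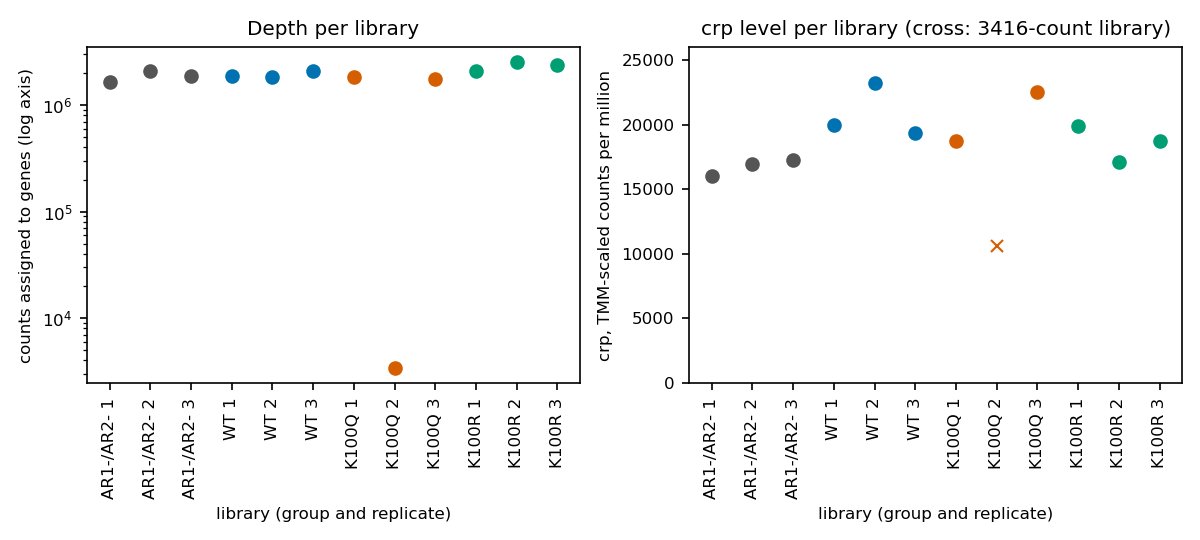
Left, reads assigned to genes per library (log axis), and right, crp in CPM, for the 4 strains and their 12 libraries; each point is a library, and the cross marks the second K100Q library. That library had 3416 reads and the others at least 1643373, and mean crp lay between 16740 and 20840 CPM.

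WT was compared with AR1-/AR2- to find the transcripts that differed when CRP could contact RNA polymerase. The comparison does not separate direct from indirect effects of those contacts. Genes for maltose uptake and tryptophan breakdown were among those with the highest increases in WT. The gene of the maltose transporter's ATPase, malK, rose from 5.76 ± 1.94 to 1842 ± 540 CPM (log2 fold change 8.31, SE 0.60, n = 3 each, adjusted p = 6.0e-10). Its binding protein gene malE (7.91) and the maltoporin gene lamB (7.97) rose with it. The tryptophanase gene tnaA rose from 40.6 ± 6.57 to 7452 ± 651 CPM (7.52, SE 0.59, adjusted p = 1.36e-09), its leader gene tnaC by 8.12 and the tryptophan permease gene tnaB by 7.14 on the log2 scale. Threonine catabolism genes tdcB (7.89) and tdcA (7.36) and the nucleoside transporter gene nupG (7.51) also rose. The nitrite reductase gene nrfC, the hydrogenase 1 gene hyaA and the fucose permease gene fucP had no read in AR1-/AR2-. They were at least 40.9-fold, at least 20.3-fold and at least 13.4-fold higher in WT. The gene yobD, of unknown function, had 706 counts in WT and 2 in AR1-/AR2-, a ratio of 279 (95% interval 77 to 2310). Leaving out 1 control library moved tnaB to 7.95 (without AR1-/AR2- replicate 3) and tdcB to 7.28 (replicate 2) or 12.54 (replicate 3). All 8 counts of tdcB in AR1-/AR2- were in replicate 3, so 12.54 is a fitted value against no read and not a measured size.

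Genes for methionine and biotin synthesis were among those with the steepest decreases in WT. The methionine synthase gene metE fell from 5547 ± 1481 to 21.4 ± 3.63 CPM (log2 fold change −8.01, SE 0.43, adjusted p = 1.96e-11), with metA (−6.53), metF (−6.51), metN (−5.27) and metR (−5.18), which serve methionine synthesis, uptake and regulation. The biotin synthase gene bioB fell from 1192 ± 395 to 4.57 ± 3.05 CPM (−7.98), with bioA (−6.85) and bioD (−5.23). The gene bioF had 415 counts in AR1-/AR2- and 1 in WT, a ratio of 525 (95% interval 93.6 to 20800). The autoaggregation factor gene flu fell from 4712 ± 965 to 33.3 ± 4.93 CPM (−7.14). Without WT replicate 1, metA was at −7.81 and metF at −7.33. Without WT replicate 3, bioA was at −7.91 and bioF at −10.26, against −8.53 with all libraries. The only WT count of bioF was in replicate 3, so −10.26 is a fitted value against no read.

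Lists of sugar and nucleoside genes rose in WT. Of 13 lactose and maltose genes, 12 rose and 1 was not called (median log2 fold change 4.90, adjusted p of the list = 6.3e-13). Of 12 galactose genes, 9 rose (median 1.71, adjusted p = 1.76e-05), among them mglB (5.76) and mglA (6.48) of the galactose transporter and the repressor gene galS (6.89). Without AR1-/AR2- replicate 1, galS was at 7.67, without replicate 2 galS was at 6.27 and mglA at 5.87, and without replicate 3 mglA was at 8.41. Of 11 nucleoside genes, 10 rose (median 3.81, adjusted p = 1.26e-12), including the cytidine deaminase gene cdd (5.85). Of 8 PTS genes, 7 rose (median 2.56, adjusted p = 3.91e-07, but adjusted p = 0.0686 with an estimated correlation). The mannose uptake gene manX rose from 80 ± 15.3 to 8800 ± 334 CPM (6.78), and the glucose uptake gene ptsG rose by 3.65. Of 26 genes for pentoses and methylpentoses, 16 rose and 1 fell (median 1.29, adjusted p = 0.0112, but adjusted p = 0.177 with an estimated correlation). Of 19 genes for sugar alcohols and amino sugars, 13 rose and 2 fell (median 1.13, adjusted p = 0.0232, but adjusted p = 0.177 with an estimated correlation). Of 13 glycerol genes, 9 rose and 3 fell (median 2.59, adjusted p = 0.0144, but adjusted p = 0.263 with an estimated correlation). Of 28 genes for amino acid catabolism, 12 rose and 7 fell (median 1.07, adjusted p = 0.0391, but adjusted p = 0.219 with an estimated correlation). The asparaginase gene ansB rose from 27.2 ± 5.84 to 3073 ± 584 CPM (6.81).

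Of 5 tested genes at class I promoters, where CRP binds upstream of RNA polymerase, 4 rose (median 7.14, adjusted p = 2.33e-04, but adjusted p = 0.0686 with an estimated correlation). Of 8 at class II promoters, where CRP overlaps the polymerase site, 6 rose (median 2.44, adjusted p = 2.22e-04, but adjusted p = 0.0622 with an estimated correlation). Of 32 genes for anaerobic respiration and fermentation, 30 rose (median 3.44, adjusted p = 4.7e-14), among them the nitrate reductase gene narH (6.23) and the hydrogenase 2 gene hybB (4.25). Of 16 acid resistance genes, 15 rose (median 4.21, adjusted p = 2.72e-10), among them the periplasmic chaperone gene hdeA (4.02) and the regulator gene gadX (4.37). Of 20 general stress genes, 18 rose and 1 fell (median 2.39, adjusted p = 3.26e-09, but adjusted p = 0.0671 with an estimated correlation), including otsB (3.85) and treA (3.65) of trehalose metabolism.

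Of 54 ribosomal protein genes, 38 fell and none rose (median −1.37, adjusted p = 3.46e-08, but adjusted p = 0.213 with an estimated correlation). The genes rpsF (−2.86) and rplD (−2.37) were among them. Of 19 iron uptake genes, 12 fell (median −1.27, adjusted p = 0.00115, but adjusted p = 0.0686 with an estimated correlation), such as tonB (−3.29), which energises uptake, and entC (−3.12) of enterobactin synthesis. Of 23 TCA cycle genes, 9 fell and 6 rose (median −0.19, adjusted p = 0.00444, but adjusted p = 0.267 with an estimated correlation). The glyoxylate shunt genes aceB (14800 ± 4625 to 673 ± 40.3 CPM; −4.46) and aceA (−4.29) fell. All 7 tested ribosomal RNA genes rose (median 3.12, adjusted p = 0.00982, but adjusted p = 0.288 with an estimated correlation). Flagella (8 of 27 rose, 1 fell; adjusted p = 0.456), heat shock (2 of 17 rose, 5 fell; adjusted p = 0.436) and acetate genes (2 of 8 rose; adjusted p = 0.206) were not called as lists. Among acetate genes the pyruvate oxidase gene poxB (3.77) and pka, the gene of a protein lysine acetyltransferase (1.99, adjusted p = 1.82e-05), rose, and the acetyl-CoA synthetase gene acs was not called (0.66, adjusted p = 0.0574), though 5 alternatives called it (0.0127 to 0.427 over the alternatives). Adjusted over the list alone, counts differed for class I (1 also lower), class II (7 higher), amino acid catabolism (8 lower), nucleosides (11 higher), flagella (6 higher), heat shock (3 lower) and iron (13 lower).

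In all, 1886 of 3391 genes were called, 1038 higher and 848 lower in WT, of which 889 and 627 changed at least 2-fold. The higher genes were 55% of the calls, but 46.3% with DESeq2 size factors, and with the length trend removed 931 were higher and 993 lower, so neither direction had the majority in every alternative. In 65.8% of the genes tested, the libraries of the strains did not overlap, where chance gives 10%. DESeq2 size factors moved the median log2 fold change of all genes by −0.187 here and by −0.228 in K100Q with AR1-/AR2-. The shift was 0.106 in K100R with WT and −0.148 in K100Q with K100R. These factors were taken over all 12 libraries, from genes with a read in each. The second K100Q library had reads in only 835 genes. In every comparison, the values with these factors therefore rest on at most those genes, and they do not show a dependence on scaling in general. The list of sugar alcohols and amino sugars was not called without AR1-/AR2- replicate 3 in WT vs AR1-/AR2- (adjusted p = 0.0758; 1.42e-05 to 0.177 over the alternatives).

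**Figure D2:**
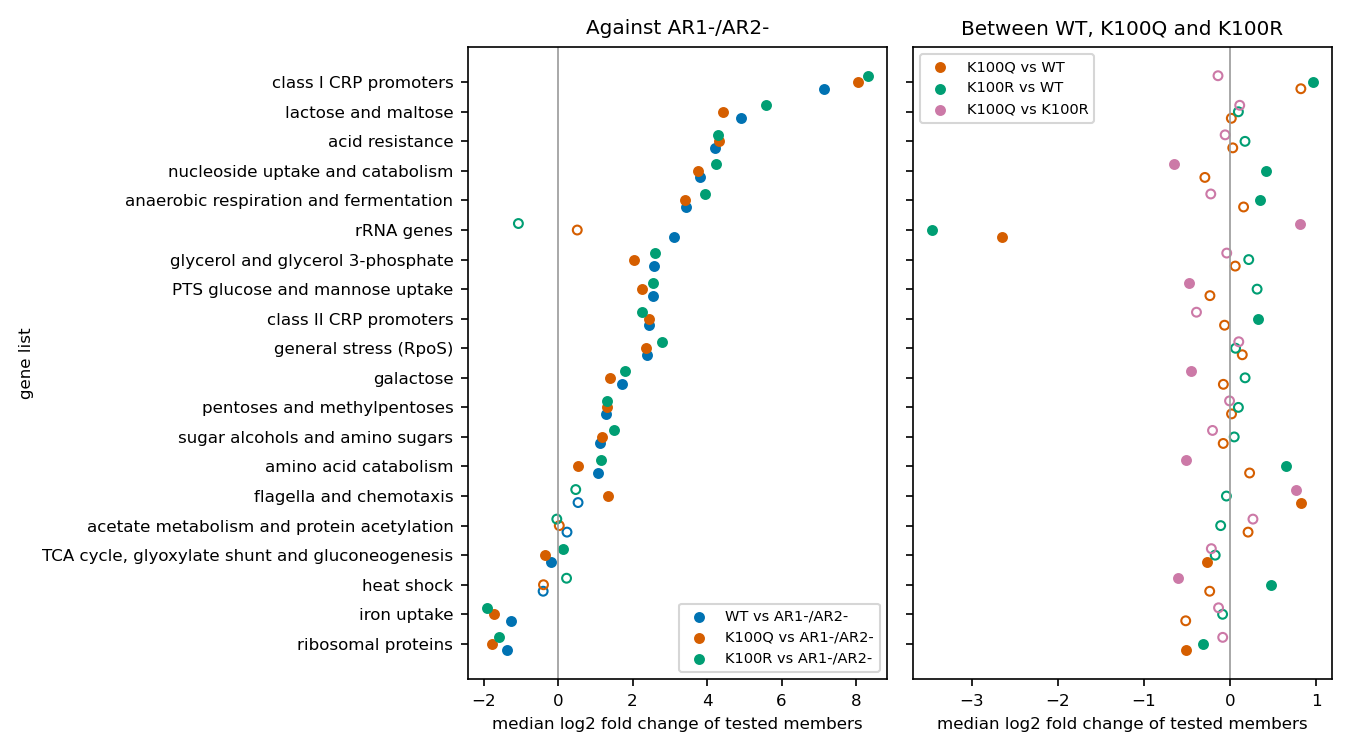
Median log2 fold change (horizontal axis) of the tested genes of each list (vertical axis), for WT, K100Q and K100R with AR1-/AR2- on the left and for the comparisons among WT, K100Q and K100R on the right; points are list medians, filled where camera with the preset correlation called the list and open where it did not. Against AR1-/AR2- the anaerobic medians were 3.44, 3.41 and 3.94, and those of ribosomal proteins −1.37, −1.78 and −1.58.

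K100Q was compared with AR1-/AR2- to find what CRP with an uncharged residue in place of K100 still changed. The same uptake and catabolism genes were among those with the highest increases. The gene malK rose from 5.76 ± 1.94 to 4097 ± 1898 CPM (n = 3 and 2, log2 fold change 9.17, SE 0.62, adjusted p = 3.31e-10) and malE to 11060 ± 3707 CPM (8.60). The gene tnaA rose to 17420 ± 2809 CPM (8.34, SE 0.61), with tnaC (8.22) and tnaB (8.05). The steepest decreases were in metE (−8.31, to 17.5 ± 2.45 CPM), metA (−7.74), bioB (−7.61) and metF (−6.70), and bioF had 1 count in K100Q against 415, a ratio of 287 (95% interval 51.2 to 11400). Without K100Q replicate 1, malK was at 8.53, metF at −9.26 and bioF at −10.30, and without K100Q replicate 3 metF was at −5.84 and bioF at −7.02 (−7.87 with all libraries). The only K100Q count of bioF was in replicate 1, so −10.30 is a fitted value against no read. Without AR1-/AR2- replicate 3, tnaB was at 8.93. The acetate genes pka (2.55, adjusted p = 1.62e-06) and acs (0.97, adjusted p = 0.0147) rose. The call of acs ended in 3 of the alternatives, among them the fit without AR1-/AR2- replicate 3 (0.72, adjusted p = 0.0673; up to 0.137 over the alternatives).

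Lists called in both WT and K100Q went the same way, and in K100Q camera called none with an estimated correlation (7 at an unadjusted p under 0.05, lowest adjusted p = 0.11), while fry called 18. Anaerobic genes rose in 31 of 32 cases (median 3.41), acid resistance in 15 of 16 (4.33), general stress in 18 of 20 (2.37), nucleosides in 11 of 11 (3.76) and lactose and maltose in 12 of 13 (4.42). Class I genes rose in 4 of 5 cases (8.05), class II in 7 of 8 (2.45), galactose in 9 of 12 (1.40), PTS in 6 of 8 (2.24) and glycerol in 8 of 13, with 1 lower (2.04). Pentoses rose in 16 of 26 cases, with 1 lower (1.30), sugar alcohols and amino sugars in 13 of 19, with 2 lower (1.18), and amino acid catabolism in 13 of 28, with 6 lower (0.53). Ribosomal proteins fell in 48 of 54 cases (median −1.78, adjusted p = 3.58e-15), iron uptake in 13 of 19 (−1.71) and TCA genes in 9 of 23, with 3 higher (−0.34). Examples are mglB (5.98), manX (6.35), cdd (5.33), hdeA (3.95) and narH (6.11) among those that rose, and aceA (−4.73) and rplI (−2.71) among those that fell. Flagellar genes rose in 18 of 27 cases, with 1 lower (median 1.34, adjusted p = 0.0075, but adjusted p = 0.399 with an estimated correlation). These included flgB of the flagellar rod (12.4 ± 6.47 to 67.3 ± 13.6 CPM; 2.44) and the flagellar sigma factor gene fliA (2.59). Acetate (3 of 8 higher; adjusted p = 0.115), heat shock (1 of 17 higher, 4 lower; adjusted p = 0.14) and ribosomal RNA (2 of 7 higher, 1 lower; adjusted p = 0.89) were not called as lists. Adjusted over the list alone, counts differed for glycerol (9 higher), PTS (7 higher) and iron (15 lower).

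The test called 1747 genes, 938 higher and 809 lower in K100Q (53.7% higher, but 44.9% with DESeq2 size factors, and 876 against 879 with the length trend removed), and the libraries did not overlap in 37.1% of genes, where chance gives 10%. The second K100Q library had reads in only 835 genes, so genes higher in K100Q could hardly part by library. The share can therefore not be set against those of WT and K100R, and the same limit holds for K100Q with WT and with K100R. In K100Q vs AR1-/AR2- the list of sugar alcohols and amino sugars was not called without AR1-/AR2- replicate 3 (adjusted p = 0.118; 0.0021 to 0.337 over the alternatives) or in the fit of 10 libraries (0.0504).

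K100R was compared with AR1-/AR2- to find what CRP changed when K100 was replaced but its positive charge was kept. The leader gene tnaC (log2 fold change 9.40, SE 1.01), tdcB (8.59) and tnaA (40.6 ± 6.57 to 14510 ± 6058 CPM; 8.48, SE 0.62, adjusted p = 3.61e-10) rose most, and nrfC was at least 63.6-fold higher. The gene yobD had 1149 counts in K100R and 2 in AR1-/AR2-, a ratio of 365 (95% interval 101 to 3020). Decreases were steepest in bioB (−8.17), metE (−8.03, to 21.1 ± 7.31 CPM), bioA (−7.15), bioF (−6.89) and metF (−6.84). Other genes that rose were manY of mannose uptake (6.83), ansB (7.82), cdd (5.98), hdeA (4.54), poxB (3.62) and pka (2.06). The genes aceB (−4.82), rplD (−3.45) and entC (−4.62) fell, and the sorbitol uptake gene srlA was at least 16.9-fold higher. The value of tdcB was 7.97 without AR1-/AR2- replicate 2, 13.24 without AR1-/AR2- replicate 3 and 7.94 without K100R replicate 1, where entC was at −5.86. Without K100R replicate 2, bioA was at −8.14, bioF at −6.26 and entC at −3.995, and without K100R replicate 3 bioB was at −8.95 and bioF at −10.24. All K100R counts of bioF were in K100R replicate 3, and all AR1-/AR2- counts of tdcB in AR1-/AR2- replicate 3. The values −10.24 and 13.24 are therefore fitted against no read.

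Called with an estimated correlation as well were anaerobic genes (31 of 32 higher, median 3.94), acid resistance (16 of 16, 4.30), nucleosides (11 of 11, 4.25), lactose and maltose (12 of 13, 5.59), galactose (10 of 12, 1.81), class II (7 of 8, 2.27) and iron uptake (14 of 19 lower, −1.91). Class I genes rose in 4 of 5 cases (median 8.33, but adjusted p = 0.0512 with an estimated correlation), PTS in 7 of 8 (2.56, but adjusted p = 0.0528 with an estimated correlation) and general stress in 17 of 20, with 1 lower (2.78, but adjusted p = 0.0512 with an estimated correlation). Pentoses rose in 15 of 26 cases, with 1 lower (1.31, but adjusted p = 0.129 with an estimated correlation). Sugar alcohols and amino sugars rose in 13 of 19, with 2 lower (1.51, but adjusted p = 0.142 with an estimated correlation). Glycerol genes rose in 9 of 13 cases, with 2 lower (2.61, but adjusted p = 0.22 with an estimated correlation), and amino acid catabolism in 14 of 28, with 5 lower (1.15, but adjusted p = 0.108 with an estimated correlation). Ribosomal proteins fell in 42 of 54 cases (median −1.58, but adjusted p = 0.145 with an estimated correlation). TCA genes were called as lower (9 of 23 lower, 3 higher; adjusted p = 0.00166, but adjusted p = 0.22 with an estimated correlation), although their median was 0.13, since their mean was −0.94. Acetate genes (2 of 8 higher; median −0.03, mean 0.62, adjusted p = 0.31), flagella (5 of 27 higher, 1 lower; adjusted p = 0.527), heat shock (5 of 17 higher, 2 lower; adjusted p = 0.749) and ribosomal RNA (3 of 7 lower; adjusted p = 0.227) were not called. Adjusted over the list alone, counts differed for pentoses (17 higher), amino acid catabolism (6 lower), general stress (18 higher), ribosomal proteins (43 lower) and ribosomal RNA (1 lower).

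The test called 1870 genes, 1028 higher and 842 lower in K100R (943 and 977 with the length trend removed), and the libraries did not overlap in 59.8% of genes, where chance gives 10%. In K100R vs AR1-/AR2- the list of sugar alcohols and amino sugars was not called without AR1-/AR2- replicate 3 (adjusted p = 0.0635; 9.4e-06 to 0.142 over the alternatives).

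Genes called against AR1-/AR2- were largely shared between the strains, with 757 higher and 604 lower in all of WT, K100Q and K100R. Independent lists of those sizes would share 87 and 50.2. WT and K100Q shared 829 higher and 679 lower (287 and 202 for independent lists), WT and K100R 893 and 724 (315 and 211), and K100Q and K100R 790 and 644 (284 and 201). In 40 simulations of unchanged groups against the same controls, the shared number was 0. Those groups were drawn around the means of the same control libraries. The simulations therefore leave out the sampling error of the controls and cannot gauge how much of the sharing comes from it. Part of the excess may come from the AR1-/AR2- libraries that the comparisons share, and 3 libraries are too few to divide between them.

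**Figure D3:**
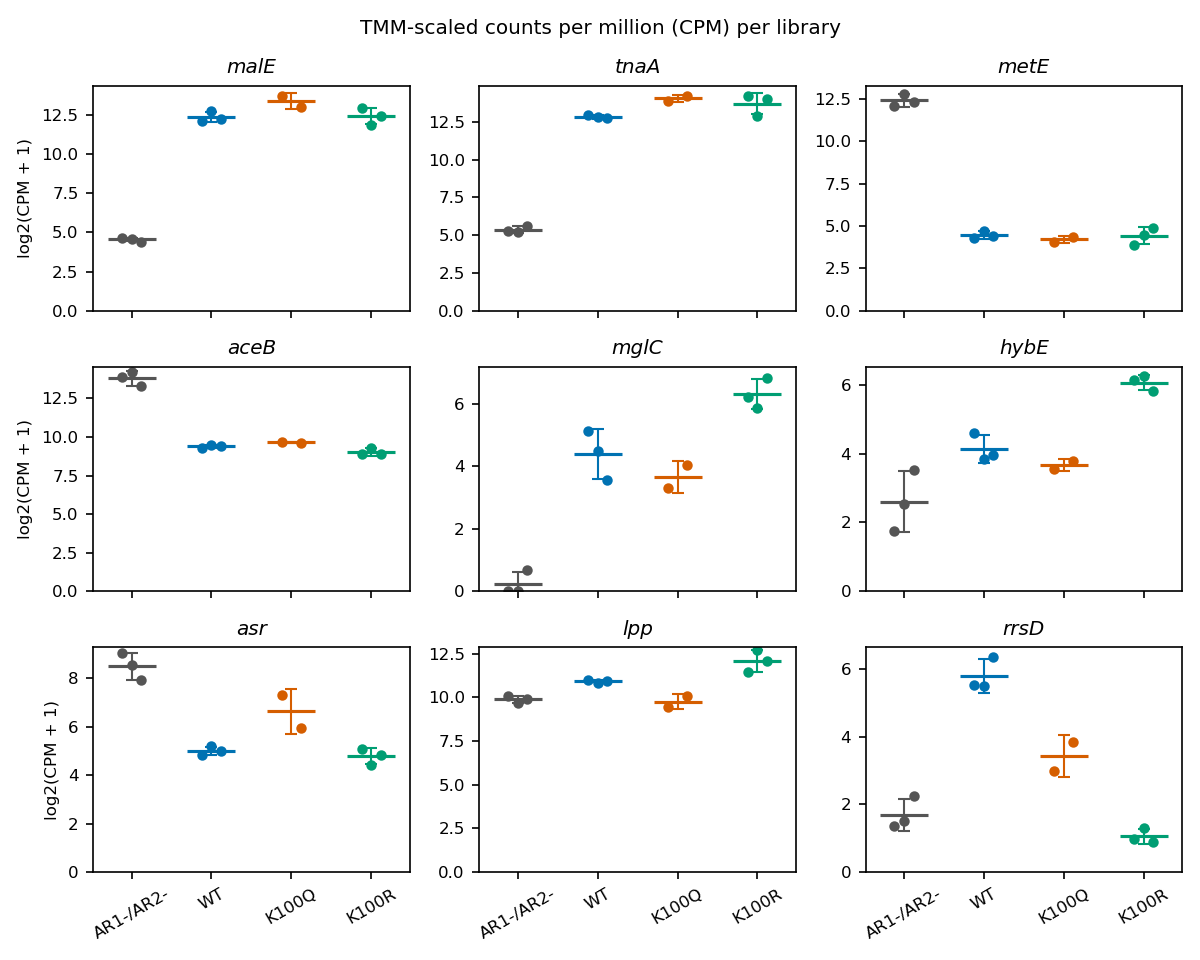
Levels of 9 named genes as log2(CPM + 1) in the 4 strains; points are libraries, horizontal lines are group means and error bars are SD, over n = 3 or, in K100Q, n = 2. Mean malE was 22.5 CPM in AR1-/AR2- and at least 5428 CPM in the other strains, and mean lpp was 4585 CPM in K100R and 882 CPM in K100Q.

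K100Q was compared with WT to find what removing the positive charge at K100 changed in CRP without the AR1-/AR2- changes. Whether K100Q itself alters the contact with RNA polymerase was not tested. The trehalose-6-phosphate hydrolase gene treC rose from 94.9 ± 36.9 CPM (n = 3) to 288 ± 19.6 CPM (n = 2; log2 fold change 1.59, SE 0.31, adjusted p = 0.0383). The acid shock gene asr rose from 31.3 ± 3.83 to 109 ± 67.5 CPM (1.89, SE 0.39, adjusted p = 0.0429), against 380 ± 141 CPM in AR1-/AR2-. Both were higher in K100Q replicates 1 and 3 than in all 3 WT libraries, while the second K100Q library had 2 reads of treC and 3 of asr, too few to count. Without K100Q replicate 1 asr was at 1.20 (adjusted p = 0.849; 0.00333 to 0.849 over the alternatives), and without K100Q replicate 3 at 2.46. The branched-chain amino acid synthesis genes ilvH (2.09, adjusted p = 0.0383) and ilvC (1.41, adjusted p = 0.0429) also rose. The ribosomal RNA genes rrsD (−2.48, adjusted p = 0.0153), rrlA (−2.65, adjusted p = 0.0382) and rrsC (−2.51, adjusted p = 0.0383) fell. Without K100Q replicate 1, rrlA was at −2.12 and rrsC at −1.88, neither of them called, and without K100Q replicate 3 they were at −3.55 and −3.70. The genes ilvH and ilvC lie outside the naming rule and were chosen after their values were seen.

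Flagellar genes were called as higher in K100Q as a list (27 tested, median log2 fold change 0.82, adjusted p = 1.17e-10, but adjusted p = 0.369 with an estimated correlation). No single one was called over all genes, and 4 were adjusted over the list alone: fliK, flgB, flgG and fliF. Ribosomal proteins were called as lower (54 tested, median −0.51, adjusted p = 4.62e-11, but adjusted p = 0.508 with an estimated correlation). TCA genes were called as lower (23 tested, median −0.27, adjusted p = 0.00716, but adjusted p = 0.612 with an estimated correlation), a call that ended without K100Q replicate 2 (adjusted p = 0.112; 3.86e-04 to 0.612 over the alternatives) and in the fit of 10 libraries (0.0705). Ribosomal RNA was called as lower (3 of 7; 7 adjusted over the list alone; median −2.65, adjusted p = 7.2e-13, but adjusted p = 0.179 with an estimated correlation). The other 16 tested lists were not called, with a lowest adjusted p = 0.161, for class I genes. That list was called as higher without K100Q replicate 2 (0.00274; 6.38e-05 to 0.628 over the alternatives), in the fit of 10 libraries and with the length trend removed, fits that all leave out that library. PTS genes were called as lower without K100Q replicate 1 (0.0191; up to 0.998 over the alternatives) and heat shock genes without K100Q replicate 3 (0.038; up to 0.803). Median, mean and test differed in sign for class II genes (−0.06, −0.05, test up), pentoses (0.02, −0.05, test up), glycerol (0.06, −0.01, test down) and general stress (0.14, −0.05, test down). Maltose, tryptophanase and galactose genes were not called, such as malE (0.69, adjusted p = 0.525), tnaA (0.82, adjusted p = 0.49), galS (−0.90, adjusted p = 0.286) and mglC (−0.87, adjusted p = 0.479). Alternatives called some of them: tnaA in the fit of 10 libraries (1.21, adjusted p = 0.0337; 0.0177 to 1 over the alternatives) and with DESeq2 on 11 libraries (1.24, 0.0177), and galS in the fit of the 6 libraries compared (−0.92, 0.0344; up to 1 over the alternatives) and with DESeq2 on 11 libraries (−0.86, 0.0493). Without K100Q replicate 2, malE was at 1.02 (0.198; 0.0741 to 1 over the alternatives).

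In all, 7 genes were called, 4 higher and 3 lower, and 386 had an unadjusted p under 0.05, where chance gives about 170. The libraries did not overlap in 18.5% of genes, where chance gives 10%. Without K100Q replicate 2, edgeR called 0 genes (459 at an unadjusted p under 0.05), the 7 then had adjusted p-values of at least 0.0708, and DESeq2 on the same 11 libraries called 58. edgeR also called 0 genes without WT replicate 3 (278 unadjusted) or K100Q replicate 1 (173 unadjusted), and 17 without K100Q replicate 3. K100Q replicate 3 was nearer to each WT library (chi-square per gene 20.5 to 26.9) than to K100Q replicate 1 (35).

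K100R was compared with WT to find what replacing K100 changed while its charge was kept. The hydrogenase 2 maturation genes hybD (15.6 ± 6.82 to 62.1 ± 17.5 CPM, n = 3 each; log2 fold change 1.99, SE 0.33, adjusted p = 0.00252) and hybE (17 ± 5.31 to 66.5 ± 10.5 CPM; 1.96, SE 0.33, adjusted p = 0.00304) rose. The galactose permease gene mglC rose from 22.1 ± 11.7 to 81.8 ± 29 CPM (1.89, SE 0.36, adjusted p = 0.0185). All 3 were higher in every K100R library than in every WT library. The ribosomal RNA genes rrsD (57 ± 21.3 to 1.09 ± 0.333 CPM; −5.59), rrsC (−4.44), rrsH (−4.18; −5.99 without K100R replicate 2) and rrlA (−3.46) fell.

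Amino acid catabolism was called as higher in K100R (28 tested, median 0.65, adjusted p = 1.43e-05; adjusted p = 0.0457 with an estimated correlation), with none called over all genes. Adjusted over the list alone, 3 were called, tdcG (2.66), tdcE (2.09) and tdcF (2.81), which belong to the threonine catabolism operon. Without K100R replicate 1 they were at 1.65, 1.30 and 2.01. Heat shock (17 tested, median 0.48, adjusted p = 6.08e-04, but adjusted p = 0.453 with an estimated correlation) and nucleosides (11 tested, 0.41, adjusted p = 0.00647, but adjusted p = 0.453 with an estimated correlation) were called as higher. So were anaerobic genes (32 tested, 0.35, adjusted p = 0.00602, but adjusted p = 0.521 with an estimated correlation). Class I genes (5 tested, 0.96, adjusted p = 0.00962, but adjusted p = 0.307 with an estimated correlation) and class II genes (8 tested, 1 of them, mglC, called over all genes and 1 adjusted over the list alone; 0.33, adjusted p = 0.00962, but adjusted p = 0.295 with an estimated correlation) were higher too. Without K100R replicate 1, the calls of nucleosides (adjusted p = 0.249; 2.39e-07 to 0.453 over the alternatives), anaerobic (0.131; 1.72e-04 to 0.521), class I (0.147; 1.75e-12 to 0.307) and class II genes (0.0779; 3.41e-04 to 0.295) ended. Without K100R replicate 3, those of nucleosides (0.0617), class I (0.0617) and class II (0.0733) ended. Ribosomal proteins were called as lower (54 tested, −0.31, adjusted p = 7.71e-05, but adjusted p = 0.521 with an estimated correlation), a call that ended without WT replicate 2 (0.0599; 7.79e-10 to 0.521). Ribosomal RNA was called as lower with both correlations (4 of 7; 7 adjusted over the list alone; median −3.46, adjusted p = 3.4e-40). The other 12 tested lists were not called, but 7 of them were in at least 1 alternative, such as galactose in 4 (higher; 0.0105 to 0.307 over the alternatives; 0.0567 in the reported test) and iron uptake in 3 (lower; 0.01 to 0.552).

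The test called 7 genes, 3 higher and 4 lower, and 380 had an unadjusted p under 0.05, where chance gives about 170. The libraries did not overlap in 19.3% of genes, where chance gives 10%. The call of hybD ended without WT replicate 3 (adjusted p = 0.0705; 1.36e-04 to 0.0817 over the alternatives), with DESeq2 (0.0758) and in the fit of the 6 libraries compared (0.0817). That of hybE ended without WT replicate 2 (0.0621; 2.6e-05 to 0.0758) or WT replicate 3 (0.0718) and with DESeq2 (0.0758). That of mglC ended without WT replicate 2 (0.123; 2.38e-04 to 0.218), WT replicate 3 (0.186), K100R replicate 3 (0.0973) or K100Q replicate 2 (0.0837), with DESeq2 (0.218), in the fit of the 6 libraries compared (0.151), with the 11 libraries thinned (0.139) and with the length trend removed (0.105). That of rrsH ended in the fit of only the 6 libraries compared (0.0585). Without K100R replicate 1, 28 genes were called. K100Q and K100R shared rrsD, rrsC and rrlA among genes lower than in WT (3, against 0.00354 for independent lists) and 0 among genes that were higher. All 3 are ribosomal RNA genes. The simulations gave 0, but they leave out the sampling error of the WT libraries that both comparisons share.

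K100Q was compared with K100R to set a residue without charge at K100 against one with charge. The outer membrane lipoprotein gene lpp fell from 4585 ± 1938 CPM in K100R (n = 3) to 882 ± 264 CPM in K100Q (n = 2; log2 fold change −2.50, SE 0.38, adjusted p = 0.00448; 4.17e-10 to 0.0498 over the alternatives). The galactose permease gene mglC fell from 81.8 ± 29 to 12.1 ± 4.64 CPM (−2.76, SE 0.46, adjusted p = 0.00592) and hybE from 66.5 ± 10.5 to 11.8 ± 1.49 CPM (−2.50, adjusted p = 0.00566). The small regulatory RNA genes gcvB (−2.96) and mcaS (−1.96) and the mechanosensitive channel gene mscS (−1.69) were lower in K100Q, as were hybD (−1.83), the transporter gene proY (−1.94), the heat shock gene hspQ (−1.84; −1.15 without K100R replicate 2, adjusted p = 0.0916; 8.16e-04 to 0.228 over the alternatives), the insertion sequence gene insL1 (−2.22) and glpQ of glycerol metabolism (−1.57). Higher in K100Q were asr (26.9 ± 6.12 to 109 ± 67.5 CPM; 2.11, adjusted p = 0.00876; 1.43 without K100Q replicate 1), yhhA (1.19), ybdK (1.04) and rrsD (3.11). The gluconate transporter gene gntP had 2 counts in K100Q and 98 in K100R, a ratio of 21.5 (95% interval 5.81 to 180). It was chosen after its values were seen. Genes called as lower in K100Q had a median length of 324 bases, against 873 over all genes tested. Of genes up to 300 bases, 16 were lower in the fit of 11 libraries and 4 with the length trend removed. Gene length is therefore not excluded for the short genes among them.

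Flagellar genes were higher in K100Q: 5 of 27 were called, and 6 adjusted over the list alone (median 0.76, adjusted p = 1.29e-07, but adjusted p = 0.248 with an estimated correlation). Among them, flgB rose from 17 ± 5.41 to 67.3 ± 13.6 CPM (1.96, SE 0.36, adjusted p = 0.0076), with the hook genes fliK (2.74; 1.76 without K100Q replicate 1) and flgE (1.42) and the basal body gene fliF (1.58). Ribosomal RNA was higher (1 of 7; 3 adjusted over the list alone; median 0.81, adjusted p = 3.08e-04, but adjusted p = 0.248 with an estimated correlation), a call that ended without K100Q replicate 3 (0.183; 4.59e-10 to 0.248 over the alternatives). Heat shock genes were lower (2 of 17 adjusted over the list alone, dnaJ and grpE; median −0.61, adjusted p = 7.93e-05, but adjusted p = 0.248 with an estimated correlation), a call that ended in the fit of 10 libraries (0.0681; 2.06e-06 to 0.248 over the alternatives). Nucleoside genes were lower (1 of 11, rihC, −1.45, and 1 adjusted over the list alone; median −0.65, adjusted p = 6.39e-04, but adjusted p = 0.248 with an estimated correlation), until K100R replicate 1 was left out (0.0557; 4.29e-07 to 0.248). PTS genes (1 of 8 adjusted over the list alone, manY; −0.47, adjusted p = 0.0189, but adjusted p = 0.399 with an estimated correlation) were lower, a call that ended without K100Q replicate 2 (0.312; 3.49e-04 to 0.399) or K100R replicate 1 (0.106), in the fit of 10 libraries (0.151) and with the length trend removed (0.308). Galactose genes (1 of 12, mglC; 3 adjusted over the list alone; −0.45, adjusted p = 0.0325, but adjusted p = 0.248 with an estimated correlation) were lower, a call that ended without K100Q replicate 3 (0.193; 0.00701 to 0.248), K100R replicate 1 (0.0971) or K100R replicate 3 (0.0628). Amino acid catabolism (1 of 28 adjusted over the list alone, sdaB; −0.51, adjusted p = 0.0378, but adjusted p = 0.248 with an estimated correlation) was lower, a call that ended without K100Q replicate 2 (0.22; 0.00122 to 0.248), K100Q replicate 3 (0.183), K100R replicate 1 (0.163) or K100R replicate 3 (0.0628), and with the length trend removed (0.203). The other 13 tested lists were not called, but 6 of them were in at least 1 alternative, such as class II genes (lower; 0.00919 to 0.324 over the alternatives) and ribosomal proteins (lower; 8.73e-04 to 0.863), each in 2. Adjusted over the list alone, they held 1 lower gene each for class II, glycerol, lactose and maltose, pentoses and general stress, and 3 for sugar alcohols and amino sugars. General stress had a median of 0.10, a mean of −0.08 and a test that pointed down (adjusted p = 0.497).

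The test called 61 genes, 31 higher and 30 lower in K100Q (50.8% higher, but 19.1% with DESeq2 size factors), and 651 had an unadjusted p under 0.05, where chance gives about 170. The libraries did not overlap in 18.7% of genes, where chance gives 10%. Without K100Q replicate 1, 3 genes were called: lpp and rrsD were among them, and the other genes named here lost their calls, such as asr (adjusted p = 0.251), mglC (0.141), hybE (0.101) and flgB (0.156). Without K100R replicate 1, 149 genes were called.

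The authors' deposited tables, at an adjusted p under 0.05, list 1020 genes as higher and 936 as lower in WT with AR1-/AR2-. They list 925 and 831 for K100Q with AR1-/AR2-, and 1027 and 900 for K100R with AR1-/AR2-. For K100Q with WT they list 29 and 20, for K100R with WT 21 and 18, and for K100Q with K100R 135 and 105. Of the calls made here, in the order given, 1801 of 1886, 1654 of 1747, 1781 of 1870, 7 of 7, 7 of 7 and 59 of 61 were also in those tables. This counts genes there with an adjusted p under 0.05 and the same sign. None of the authors' calls had the opposite sign here. The deposited mean normalized counts of WT with AR1-/AR2- were within 1% of the mean over 11 libraries, without the second K100Q library, for 2161 of 2161 genes, and of the mean over 12 libraries for 2.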

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

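The tests of explanations in this part were all chosen after the results were seen, apart from the counts of other splits, which were planned. Reads in no annotated gene averaged 10.1% in WT, 10.2% in K100Q (replicates 1 and 3) and 9.31% in K100R, each above the highest AR1-/AR2- library (4.93%), in data that the comparisons of genes do not use. Reads that were not aligned averaged 5.34% in WT, 5.5% in K100Q (replicates 1 and 3) and 6.9% in K100R, also above the highest AR1-/AR2- library (5.302%), but the lowest libraries of WT (5.227%) and K100R (5.297%) were not. K100R replicate 2 stood apart from the other K100R libraries, with 5.6% of reads in no annotated gene and 9.7% not aligned. Its gene counts stood apart as well, with a chi-square per gene of 68.1 to K100R replicate 1 and 48.5 to K100R replicate 3. Those 2 lay at 14.4 from each other and at 21 to 34.1 from the WT libraries, nearer than to K100R replicate 2.

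The second K100Q library had 3416 gene counts, against at least 1643373 in each of the others. Reads carried over from an equal mix of the deeper libraries would have given 32 counts (lower Poisson bound 21) in a set of 16 genes. These were at least 16-fold lower in the other strains than in AR1-/AR2-, and 5 counts were found. The genes were chosen in fits that include this library, so genes with many reads there could drop out. The count therefore cannot decide against an equal mix. Carry-over mainly from WT, K100Q or K100R libraries stays open. The 16 genes had 1464 CPM before TMM scaling here, and 949.9 to 1476 CPM in the deeper libraries of those strains. WT reads under a K100Q label stay open: the log-likelihood of the library's reads was higher by 124.1 under the nearest WT library than under the nearest K100Q library. K100Q replicate 3 thinned to the same depth also preferred WT in 20 of 20 draws (mean difference 106.6), and at full depth it was nearer to each WT library (chi-square per gene 20.5 to 26.9) than to K100Q replicate 1 (35), whose draws preferred their own group (−153.4), so a wrong label and a difference between K100Q libraries cannot be told apart. A low amount of input RNA or a failed library was not tested.

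Short genes differed between libraries, which may have shaped calls: those of up to 150 bases had a median log2 deviation of −0.80 to −0.34 in AR1-/AR2- libraries, 0.12 to 0.29 in WT, 0.32 to 0.57 in K100R, −0.26 in K100Q replicate 1 and 0.11 in K100Q replicate 3. With a smooth trend on coding length removed from each of 11 libraries, 90.8% of the calls of WT with AR1-/AR2- were made again in the same direction, which argues against gene length as the source of most of those calls. It did not exclude gene length for the 350 genes of up to 300 bases, whose median log2 fold change in that comparison went from 0.79 to −0.039, with 154 higher and 26 lower before and 99 and 79 after. Of the same genes, 9 were higher and 16 lower in K100Q than in K100R in the fit of 11 libraries, against 15 and 4 with the trend removed. Whether these shifts come from a library effect or from short genes that the strains express differently stays open, since a correction on length removes both.

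Ribosomal RNA reads were higher in WT, with 653 ± 256 CPM before TMM scaling (n = 3) against 111 ± 24.9 in AR1-/AR2- (n = 3), 94.5 ± 80.4 in K100Q (n = 2) and 61.1 ± 56.8 in K100R (n = 3). Reads divided between near-identical copies would leave their sum as it is. The lowest WT library exceeded the highest other deep library by 3.13 times, which argues against division alone as the source. Reads left uncounted because they align to several copies would lower the sum. How such reads were counted is not given, so that source stays open. Unequal removal of ribosomal RNA before sequencing stays open, since libraries within K100R differed by 5.53 times and the removal was not measured. A difference in ribosomal RNA between the strains themselves was not tested and stays open as well.

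Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05, and in each 1 split of the 10, the real one, gave a count as large as its own. For WT with AR1-/AR2- the real split called 1886 genes and the highest of the other splits 0, for K100Q with AR1-/AR2- 1747 and 489, and for K100R with AR1-/AR2- 1870 and 0. For K100Q with WT the counts were 7 and 0, for K100R with WT 7 and 0, and for K100Q with K100R 61 and 27. The splits were fitted with edgeR only, and where the highest other count was 0, other splits had up to 130 (WT with AR1-/AR2-), 295 (K100R with AR1-/AR2-), 185 (K100Q with WT) and 219 genes (K100R with WT) at an unadjusted p under 0.05. The split of 489 put the second K100Q library with AR1-/AR2- replicates 1 and 2, and that of 27 put K100R replicate 1 with K100Q replicates 1 and 3. Both moved the second K100Q library, with its 3416 counts, to the other side. Among the deeper libraries they still mostly followed strain, so they do not show a parting by more than strain.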

How the results depend on the processing

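The fits of 11 and 10 libraries, DESeq2 on 11 libraries, thinning of the 11 and the removal of the length trend were chosen after the data were seen; the others were planned. Against AR1-/AR2-, the counts of called genes stayed within 1.5 times of the main ones in every alternative but thinning all libraries to the shallowest, which left 60 for WT, 55 for K100Q and 63 for K100R because few genes could be tested. Leaving out 1 library gave 1628 to 1977, 1412 to 1828 and 1631 to 1953. Of the named genes, 61 of 66, 25 of 27 and 27 of 29 stayed past the threshold in every alternative that tested them, against 0 of 7 for K100Q with WT, 3 of 7 for K100R with WT and 1 of 25 for K100Q with K100R. Thinning all libraries tested only 12, 6, 5, 0, 0 and 1 of these genes, and the 3 for K100R with WT are ribosomal RNA genes, which 1 alternative leaves out. Of the named genes that were not called, 2 of 2, 2 of 2, 2 of 2, 7 of 11, 10 of 11 and 5 of 5 were called in at least 1 alternative, in the same order.

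For K100Q with WT (7 genes), DESeq2 on 12 libraries called 1, the 6 libraries alone 111, voom 31, the 10 libraries 19 and DESeq2 on 11 libraries 58. edgeR called 0 (genes at an unadjusted p under 0.05 in brackets) with all libraries thinned (5), without crp and the ribosomal and transfer RNA genes (378), with the 11 thinned (453) and with the length trend removed (463). Leaving out 1 library gave 0 to 17: 2 without WT replicate 1, 4 without WT replicate 2, 0 without WT replicate 3, K100Q replicate 1 or K100Q replicate 2, and 17 without K100Q replicate 3. For K100R with WT (7 genes), voom called 196, the fit without crp and the ribosomal and transfer RNA genes 3, all libraries thinned 1, the 10 libraries 15 and DESeq2 on 11 libraries 44. Leaving out 1 library gave 4 to 28: 11 without WT replicate 1 or K100R replicate 2, 4 without WT replicate 3 and 28 without K100R replicate 1. For K100Q with K100R (61 genes), DESeq2 on 12 libraries called 40, size factors 131, the filter of 10 CPM 102, the 6 libraries alone 176, all libraries thinned 2 and DESeq2 on 11 libraries 253. Leaving out 1 library gave 3 to 149: 3 without K100Q replicate 1, 104 without K100Q replicate 2, 34 without K100Q replicate 3, 149 without K100R replicate 1 and 29 without K100R replicate 3. The fit of 11 libraries called 63 as higher and 41 as lower, and with the length trend removed as well these were 64 and 24. Apart from thinning, which lowers depth, the cause was not tested.

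With an estimated correlation, 5 of 17 lists called stayed for WT with AR1-/AR2-, 0 of 17 for K100Q with AR1-/AR2-, 7 of 16 for K100R with AR1-/AR2-, 0 of 4 for K100Q with WT, 2 of 8 for K100R with WT and 0 of 7 for K100Q with K100R. Where that left 0, camera had 7, 2 and 2 lists at an unadjusted p under 0.05. Fry called 18 lists for K100Q with AR1-/AR2-, 0 for K100Q with WT (4 unadjusted), 1 for K100R with WT and 4 for K100Q with K100R, and the fit of 10 libraries called 14 for K100R with WT. Leaving out 1 library gave 4 (without K100R replicate 1) to 13 (without K100R replicate 2) lists for K100R with WT, and 3 (without K100R replicate 1) to 10 (without K100Q replicate 1) for K100Q with K100R. Of the lists that were not called, 2 of 3 for WT with AR1-/AR2-, 2 of 3 for K100Q with AR1-/AR2-, 1 of 4 for K100R with AR1-/AR2-, 3 of 16 for K100Q with WT, 7 of 12 for K100R with WT and 6 of 13 for K100Q with K100R were called in at least 1 alternative. The log2 fold change of crp in K100Q with AR1-/AR2- turned to −0.084 with DESeq2 and −0.090 with its size factors, and leaving out 1 library gave −0.17 (without K100Q replicate 3) to 0.26. In K100R it turned to −0.025 with the length trend removed. The DESeq2 size factors rest on genes with a read in all 12 libraries, at most the 835 of the second K100Q library. Whether this turned the sign in K100Q was not tested, and neither was the cause in K100R.

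The replicate numbers are not stated to mark a shared day. Of 15 pairs of libraries with the same number, 5 had a correlation of their deviations over 0.1 (from −0.08 to 0.30). Pairs with other numbers lay from −0.30 to 0.16, and 6 of 11 libraries correlated best with their own number. These values do not exclude a shared effect of the number. The numbers were not taken to pair the samples because the labels do not say that they do. With the number as a block, 12 genes were called for K100Q with WT and 31 for K100R with WT, and the other counts stayed within 1.5 times. Depth limits all values of the second K100Q library, where genes under 371 CPM (TMM-scaled) have fewer than 3 counts.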

Other observations

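The groups of genes here were put together after their values were seen. Of 15 genes for methionine synthesis and uptake, 14 were lower in WT than in AR1-/AR2-, 13 in K100Q and 14 in K100R, with median log2 fold changes of −3.16, −3.74 and −3.57. Besides metE, they included the transporter gene metQ (−4.09 in WT), the synthetase gene metK (−3.12) and the repressor gene metJ (−1.12), while mmuM was not called (0.09, adjusted p = 0.844). Of 7 genes for biotin, 5, 5 and 6 were lower, with medians of −5.23, −5.46 and −5.04. The repressor gene birA was not called in WT (−0.47, adjusted p = 0.108), and neither was bioH (−0.11, adjusted p = 0.815). Of 10 genes made up of the type 1 fimbriae genes and flu, 9 were higher and 1, flu, was lower in each of the 3 strains. In WT the main subunit gene fimA rose by 5.24 on the log2 scale, the adhesin gene fimH by 4.01 and the recombinase genes fimB and fimE by 1.10 and 3.38.

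In K100Q with K100R, the genes ilvH (1.54), yhcO (1.78), flgG (1.46, adjusted p = 0.0494) and atpE (−1.30) were also called. They were chosen after their values were seen, and none of these calls was made without K100Q replicate 1, where flgG was at 0.61. DESeq2 on the 11 libraries called 1950 genes for WT with AR1-/AR2-, 58 for K100Q with WT, 44 for K100R with WT and 253 for K100Q with K100R. Of these, 1948, 41, 39 and 238 are in the authors' deposited tables at an adjusted p under 0.05 and with the same sign. Genes that those tables hold at an adjusted p from 0.05 to 0.1 were not counted.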
